A study of Mus musculus with 16 samples.

How the data were processed

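Poly(A)-selected RNA from the prefrontal cortex of male C57BL/6J mice was sequenced in 16 libraries, 4 for each combination of stress history (naive or chronic variable stress) and injection (saline or vitamin B12). The submitters' processing notes name bcl2fastq 2.20.0.422, featureCounts and DESeq2, with no version for the last pair, and the builds GRCm38 and mm10; the aligner, the annotation and the strand setting are not given in the sources used here. Of the deposited tables, the first holds counts, whole numbers of reads per Ensembl gene and library. The second deposited table holds TPM, and count divided by TPM gives a single length per gene in every library, so that it adds no measurement to the counts. The third deposited table holds log2 values that the authors made with a variance-stabilizing transformation, as its name and values show. Of the 53715 gene identifiers, 53620 were matched to GENCODE M21 on GRCm38 for symbols, positions and gene lengths; the 95 unmatched identifiers hold 0.0239% of all reads. Each group of the labels was used as given, and no library was left out of the analysis. The labels number the libraries 1 to 4 in each group without stating separate animals, so that p-values measure the spread between these libraries.

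Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered by filterByExpr on the 4 groups, which kept 18041, libraries were scaled by TMM, and 1 mean per group was fitted to all 16 libraries by edgeR's quasi-likelihood method with robust estimates. The comparisons were stress under saline, vitamin B12 in stressed mice, vitamin B12 in naive mice, stress under vitamin B12, the difference between the 2 vitamin B12 responses (the interaction), and stress and vitamin B12 each averaged over the other factor. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05; a gene that passed is said to have risen or fallen. The standard error of a log2 fold change is its size over the square root of the F statistic. Group levels are means ± SD of TMM-normalized CPM (n = 4), and values of single libraries are plain CPM of all counted reads, except those of the closing part on single libraries far from their group, which are TMM-normalized.

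Before the data were examined, the comparisons, the tests, the gene lists, the settings to vary and the rule for named genes were fixed. The rule names Ttr, the 10 genes that rose most and the 10 that fell most among genes past the threshold with a mean of at least 1 CPM and a symbol that is not a predicted name, filled up to 5 per direction with the lowest unadjusted p among genes that did not pass, up to 4 members of each list that passed, and at most 2 of each other list; for the 2 averaged comparisons it names the 5 that rose most and the 5 that fell most. The lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with the correlation between genes estimated per list and adjusted over the 29 lists with at least 5 tested members; the remaining list of the 30 served to check the sex of the libraries. The lists hold markers of choroid plexus, ependyma, meningeal fibroblasts, mural cells, endothelium, astrocytes, microglia, myelin, oligodendrocyte precursors, glutamatergic neurons, GABAergic interneurons, striatum, olfactory bulb and blood, and genes of the immediate-early response, the glucocorticoid response, stress neuropeptides, the vitamin B12, folate and methionine cycle, chromatin methylation, RNA methylation, thyroid hormone and retinoid signalling, the synapse, oxidative phosphorylation (nuclear and mitochondrial), the cytosolic ribosome, inflammation and interferon, the circadian clock, heat shock and the unfolded protein response. Counts "adjusted over the list alone" use the Benjamini-Hochberg method within a list.

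Agreement between comparisons that share no library is Pearson's r across genes, with a two-sided permutation p from 4900 relabellings of the libraries within each arm and adjusted over both such relations; genes are not independent replicates, and the permutation of libraries allows for that. The stress and vitamin B12 comparisons that share the stressed saline libraries were set beside 1000 simulated sets of unchanged groups. The settings varied were DESeq2 1.42.0 as test and for size factors, limma voom with sample quality weights, limma-trend on the deposited log2 values, no filter and a filter of 1 CPM in 8 libraries, non-robust estimates, an adjusted p under 0.1, the replicate number as a block, the mean of the choroid plexus list as a covariate, fits to the compared groups alone, camera with a preset correlation of 0.01, fry, a mean of at least 5 CPM or Spearman's rho for the agreements, the same without genes of the choroid plexus, ependyma, meninges and blood lists, and leaving out each library in turn. Fits without stressed vitamin B12 libraries 1 and 3, without stressed saline libraries 3 and 4 and without these 4, and the clock list without its genes shared with the glucocorticoid list, were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

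The fit was tested on simulated data with 200 changed genes among 18041, 100 at each fold. For stress under saline it recovered 51% of 1.5-fold and 83% of 2-fold changes, and for the vitamin B12 comparison in stressed mice 50% and 78%. With changes added to the real libraries, it recovered 54% and 84% for stress under saline and 37% and 80% for vitamin B12 in stressed mice. In a simulated list shifted 1.3-fold, camera gave an adjusted p of 4.2e-07, and 0 unshifted lists passed. The simulated genes were drawn independently, while the estimated correlation within a real list reached 0.86, in the blood list. The simulation therefore does not tell whether camera would find such a shift in a list of correlated genes. Depth limits the single-library values of scarce genes: a count of 0 allows up to 3 reads, and 95% Wilson intervals are given for shares of single libraries. These intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules.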

Results

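Prefrontal cortex RNA was compared between male C57BL/6J mice aged 10 weeks that were naive or had gone through chronic variable stress, a paradigm of 21 days in which tube restraint, tail suspension and foot shocks alternated for 1 h each. Within each history the mice had received an injection of saline or of vitamin B12, a cofactor of methionine synthesis. The dose is not given in the labels, which place the injections on the last day of stress, while the design text places them after it. All were kept on chow with 50 mg/kg of the vitamin. Each of the 4 groups had 4 libraries. Counted reads came to 19.2 ± 2.15 M per library in naive saline, 22.7 ± 6.17 M in stressed saline, 20.3 ± 1.54 M in naive vitamin B12 and 19.1 ± 2.48 M in stressed vitamin B12 (SD, n = 4). The labels number the libraries of a group without stating separate animals. Single libraries held 16.89 to 31.65 M reads, and 18041 genes entered the tests. Mitochondrial transcripts took 4.83% to 6.22% of reads, with 95% Wilson intervals at most 0.023 percentage points wide. Xist, which marks female tissue, reached at most 0.429 CPM (0.217 to 0.846), and the Y-linked gene Ddx3y at least 61.0 (57.4 to 64.9).

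Marker genes of other brain regions and a trend with gene length set single libraries apart. In stressed vitamin B12 library 1, the 11 tested olfactory bulb markers lay above all 15 other libraries, by a median log2 difference of 4.35. Cdhr1, a cadherin of olfactory bulb mitral cells, stood at 284 CPM (95% Wilson interval 276 to 292) against a median of 3.23 in the other libraries, and Th, which makes dopamine in bulb interneurons, at 76.9 (73.0 to 81.1) against 0.929. Eomes, a transcription factor of mitral cells, stood at 50.8 (47.7 to 54.3) against at most 0.161. Neurod6, a transcription factor of cortical projection neurons, was lower there at 62.3 (58.8 to 66.1) against a median of 125.5, and Gad1, the enzyme of GABA synthesis, was higher at 896 (883 to 910) against 196. Stressed vitamin B12 library 3 deviated from the median library with gene length, at a rank correlation across genes of -0.51, where the other 15 libraries lay between -0.29 and 0.29. In the same library, nuclear-encoded genes of oxidative phosphorylation had a median log2 difference of 0.57, genes of the cytosolic ribosome 0.45 and synapse genes -0.44 from the other 15 libraries. Myelin genes, transcribed by oligodendrocytes, lay above the other libraries by a median of 0.98 in naive vitamin B12 library 3, 0.58 in stressed vitamin B12 library 1 and 0.61 in library 3 of that group. The first 2 principal components, with 22.2% and 16.0% of the variance, set stressed vitamin B12 libraries 1 and 3 apart from the rest.

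**Figure D1:**
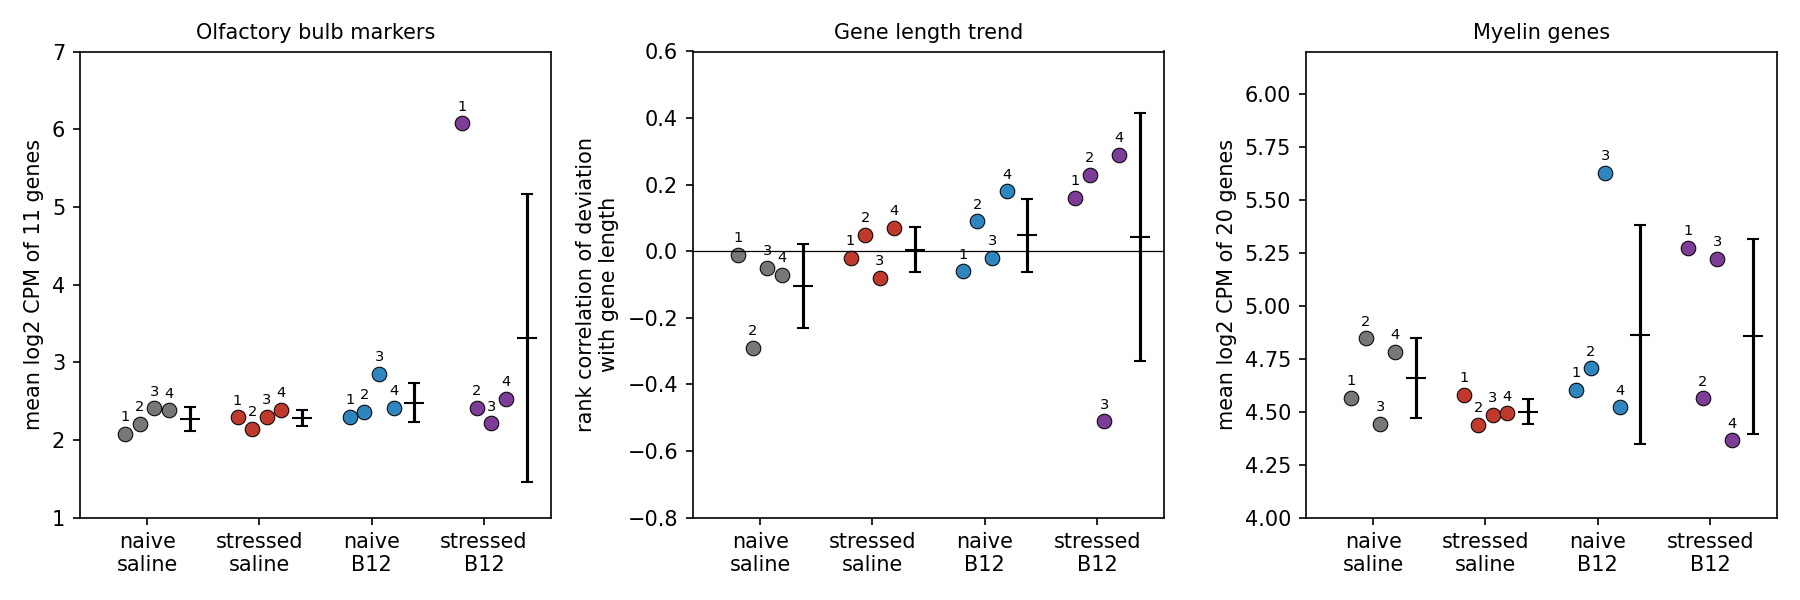
Per-library scores in the 4 groups: mean log2 CPM of 11 olfactory bulb markers, rank correlation across genes of each library's deviation with gene length, and mean log2 CPM of 20 myelin genes. Points are libraries with their replicate numbers and bars are group means ± SD; stressed vitamin B12 library 1 lies at 6.08 for the olfactory markers and library 3 at -0.51 for gene length.

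Ttr (ENSMUSG00000061808, chromosome 18, 20665280 to 20674321, GRCm38) encodes transthyretin, the carrier of thyroxine and retinol that the choroid plexus secretes and that the series title names. Its transcript was abundant in 2 of the 16 libraries, both of stressed saline: library 3 held 248 CPM (95% Wilson interval 241 to 256) and library 4 held 1899 (1880 to 1920). The other stressed saline libraries held 0.474 (0.287 to 0.782) and 1.08 (0.723 to 1.63), inside the range of the naive saline libraries, 0.290 (0.124 to 0.679) to 1.52 (1.07 to 2.15). Under vitamin B12, naive library 1 held 16.9 (15.2 to 18.7) and stressed library 3 held 8.70 (7.41 to 10.2). Stressed vitamin B12 library 2 held 0 reads of Ttr, which allows up to 0.159 CPM, and the remaining libraries reached at most 1.54 (1.08 to 2.19). The 11 tested choroid plexus markers other than Ttr lay above the other 14 libraries by a median log2 difference of 1.5 in stressed saline library 3 and 4.23 in library 4. Clic6, a chloride channel protein of the choroid plexus, stood at 6.59 (5.49 to 7.91) and 33.4 (31.0 to 36.0) against a median of 0.229, and Enpp2, a lysophospholipase that the choroid plexus secretes, at 290.3 (282 to 298) and 951 (938 to 964) against 206.

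Ttr did not pass edgeR's quasi-likelihood test in any comparison. Its group levels were 0.859 ± 0.521 CPM in naive saline, 543 ± 925 in stressed saline, 4.89 ± 7.99 in naive vitamin B12 and 2.31 ± 4.14 in stressed vitamin B12 (SD, n = 4). The log2 fold change was 9.25 ± 2.51 for stress under saline (SE, adjusted p = 0.256 in edgeR), with 2 of the 4 stressed libraries above all naive ones, and -7.97 ± 2.29 for vitamin B12 in stressed mice (adjusted p = 0.848 in edgeR). It was 2.48 ± 2.69 for vitamin B12 in naive mice (adjusted p = 1 in edgeR), -1.19 ± 2.31 for stress under vitamin B12 (adjusted p = 0.937) and -10.44 ± 3.33 for the interaction (adjusted p = 0.999). Without naive vitamin B12 library 1 the value for vitamin B12 in naive mice was 0.01 ± 3.7 and that for stress under vitamin B12 turned to 1.29 ± 3.14. Averaged over the other factor, Ttr gave 4.03 ± 1.79 for stress (adjusted p = 0.471 in edgeR) and -2.74 ± 2.1 for vitamin B12 (adjusted p = 1). DESeq2 called Ttr for stress under saline at 9.30 ± 1.79 (adjusted p = 0.000102). Without stressed saline libraries 3 and 4 the value for stress under saline was -0.20 ± 1.96 (adjusted p = 1 in edgeR). In that fit the value for vitamin B12 in stressed mice turned to 1.56 ± 1.88, and the interaction stood at -0.92 ± 2.37.

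**Figure D2:**
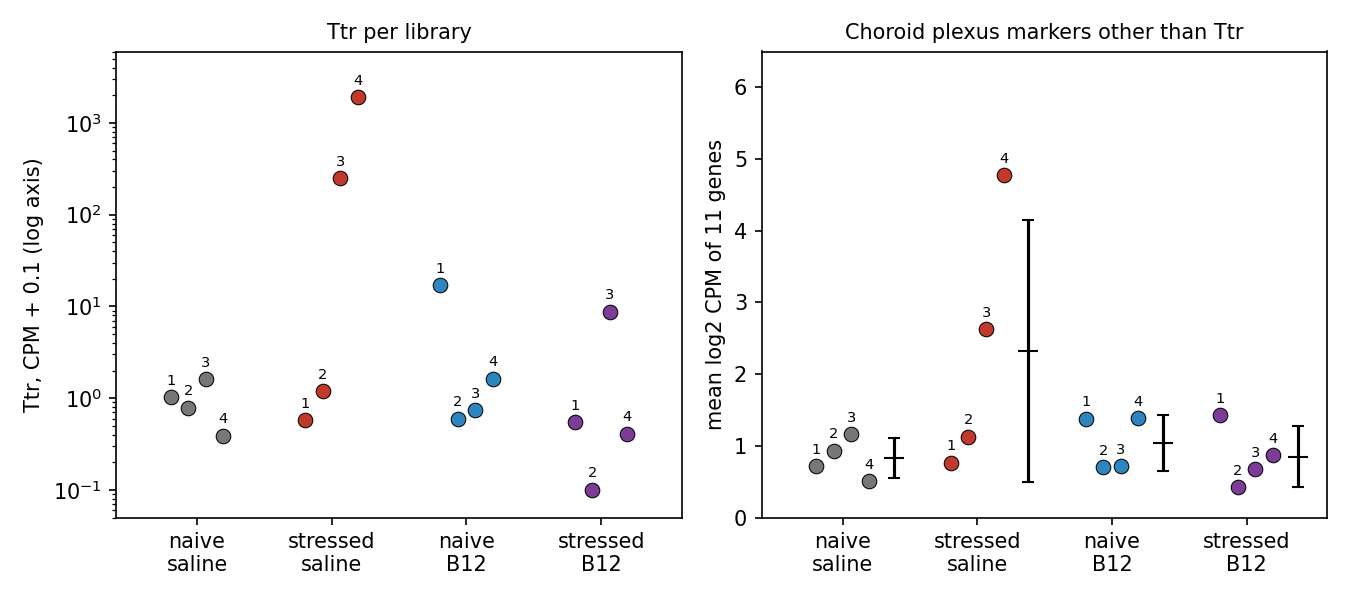
Ttr in CPM plus 0.1 on a log axis, and the mean log2 CPM of 11 other choroid plexus markers, per library in the 4 groups. Numbers are replicates and bars are group means ± SD; stressed saline libraries 3 and 4, with 248 and 1899 CPM of Ttr, are also the highest for the markers.

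The comparison of stressed with naive mice under saline asks which transcripts differed after chronic variable stress. Repeated stress and its last stressor cannot be told apart in it, since no group had a single stressor alone. Zfp189, a zinc finger transcription factor, rose from 8.21 ± 0.931 to 19.3 ± 3.17 CPM (SD, n = 4), a log2 fold change of 1.23 ± 0.13 (SE, adjusted p = 0.000272, edgeR's quasi-likelihood test). Tnfrsf25, a death receptor of the TNF receptor family, rose from 1.16 ± 0.482 to 3.69 ± 0.403 CPM (1.67 ± 0.28, adjusted p = 0.00804, edgeR). Ddit4, an inhibitor of mTOR signalling, rose from 23.7 ± 4.61 to 52.9 ± 5.42 CPM (1.16 ± 0.17, adjusted p = 0.00529, edgeR), and Acer2, an alkaline ceramidase, from 6.65 ± 0.797 to 13.7 ± 1.67 CPM (1.04 ± 0.14, adjusted p = 0.00273). Plin4, which coats lipid droplets, rose by 1.34 ± 0.26, the transcription factor Maff by 1.27 ± 0.22, the kinase Sik1 by 1.19 ± 0.24, the small GTPase Arl4d by 1.03 ± 0.20, Ier5l by 1.03 ± 0.18 and Fam78a by 1.01 ± 0.16 on the log2 scale. Edn1, which encodes the vasoconstrictor peptide endothelin, fell from 2.52 ± 0.26 to 1.11 ± 0.156 CPM (-1.18 ± 0.23, adjusted p = 0.0256, edgeR). The opsin gene Opn3 fell by 0.75 ± 0.14, and the transcription factors Ets1 and Klf6 by 0.58 ± 0.10 and 0.37 ± 0.07. Mplkip did not pass, at -0.48 ± 0.11 (adjusted p = 0.0784, edgeR). For each of these genes the 4 stressed libraries lay beyond all 4 naive ones, which chance gives for 2.86% of genes not chosen, as these were, by the same test.

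In all, 69 genes passed edgeR's test under saline, of which 62 rose and 7 fell, with a median log2 fold change of 0.68 in size; 1254 genes had an unadjusted p under 0.05. Of the 23 called genes named for this comparison, Zfp189, Tnfrsf25, Ddit4, Acer2, Fam78a, Per1, Tsc22d3, Fkbp5, Rara and Sox8 passed without each of the 8 libraries in turn. Edn1, Klf6 and Sik1 passed in none of these 8 fits, and the other 10 named genes lost the call in 1 to 7 of them. Without naive saline library 1, 2, 3 or 4 the count was 24, 45, 30 or 37, and without stressed saline library 1, 2, 3 or 4 it was 30, 35, 35 or 31. Without stressed saline libraries 3 and 4, the pair with choroid plexus transcripts, 1 gene passed: Zfp189, at 1.42 ± 0.13 (adjusted p = 0.000197, edgeR), named here after its values were seen. Without these 2 and stressed vitamin B12 libraries 1 and 3 together, 224 genes passed, 67 of them among the 69. The count was 168 in DESeq2, 479 in limma voom, 515 in a fit to these 8 libraries alone and 23 with the mean of the choroid plexus list as a covariate.

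Glucocorticoid-responsive genes rose together under saline. Of the 31 tested members, 10 rose, 0 fell and 21 did not pass over all genes, and 20 rose adjusted over the list alone. In all, 29 had a positive log2 fold change, at a median of 0.43 (adjusted p = 0.000138, camera with an estimated correlation). Fkbp5, the co-chaperone that restrains the glucocorticoid receptor, rose from 28.2 ± 1.88 to 43.0 ± 5.23 CPM (0.61 ± 0.09, adjusted p = 0.00529, edgeR). Tsc22d3, the glucocorticoid-induced leucine zipper, rose from 53.6 ± 5.12 to 91.3 ± 6.39 CPM (0.77 ± 0.11, adjusted p = 0.00529, edgeR), and the clock gene Per1 from 67.3 ± 7.85 to 108 ± 8.49 CPM (0.69 ± 0.09, adjusted p = 0.00273). Plin4 and Ddit4 also belong to this list. In the circadian clock list, 3 of 19 tested members rose, 0 fell and 16 did not pass, and 6 rose adjusted over the list alone. The median was 0.22 and 17 were positive (adjusted p = 0.0491, camera with an estimated correlation). Its transcriptional repressors Bhlhe40 and Bhlhe41 rose by 0.63 ± 0.12 and 0.45 ± 0.08 (adjusted p = 0.0198 and 0.0203, edgeR), while Per2 did not pass, at 0.63 ± 0.15 (adjusted p = 0.118). Without Per1, which both lists hold, the clock list gave an adjusted p of 0.10 in camera. The glucocorticoid list passed without each of the 8 libraries in turn. The clock list passed without naive saline library 3 (adjusted p = 0.0349, camera). It lost the call without naive saline library 1, 2 or 4 (adjusted p = 0.0578, 0.0545 and 0.0691, camera) and without stressed saline library 1, 2, 3 or 4 (adjusted p = 0.0951, 0.0537, 0.0532 and 0.0778, camera). The call also ended with the choroid plexus covariate and with the replicate block (adjusted p = 0.113 and 0.0587, camera), at a median of 0.22 in both. Without stressed saline libraries 3 and 4 the median was 0.19 (adjusted p = 0.136, camera).

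Other lists did not pass camera under saline. Among the 35 immediate-early genes, which respond to neuronal activity, 4 rose, 0 fell and 31 did not pass, against 8 up and 1 down adjusted over the list alone (median 0.28, adjusted p = 0.191, camera); Fosb rose by 0.83 ± 0.14 (adjusted p = 0.00768, edgeR). Of 34 genes of thyroid hormone and retinoid signalling, 1 rose, the retinoic acid receptor Rara, by 0.85 ± 0.13 (adjusted p = 0.00529, edgeR), also 1 adjusted over the list alone (median 0.05, adjusted p = 0.174, camera). This list passed camera without naive saline library 3 (adjusted p = 0.0263). The 11 choroid plexus markers had a median of 2.34 with 0 passed over all genes and 11 up adjusted over the list alone (adjusted p = 0.405, camera). They were high in stressed saline libraries 3 and 4. In endothelium, Slc2a1, the glucose transporter of the blood-brain barrier, rose by 0.48 ± 0.09 (adjusted p = 0.0275, edgeR), and it was the 1 of 16 tested markers that passed. Adjusted over the list alone, 1 was up and 2 down (median -0.04, adjusted p = 0.984, camera). The tight junction gene Cldn5 did not pass, at -0.56 ± 0.17. Of 13 oligodendrocyte precursor markers 1 rose, the transcription factor Sox8, by 0.68 ± 0.11 (adjusted p = 0.00703, edgeR), also 1 adjusted over the list alone (median -0.04, adjusted p = 0.984, camera). In the heat shock list 0 of 25 passed and 3 rose adjusted over the list alone (median 0.05, adjusted p = 0.405, camera), with the small heat shock gene Hspb1 at 0.92 ± 0.20. In the unfolded protein response 0 of 31 passed and 4 rose adjusted over the list alone (median 0.01, adjusted p = 0.68, camera).

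No member passed over all genes under saline in the vitamin B12, folate and methionine list (53 tested, median 0.01, adjusted p = 0.984, camera) or among stress neuropeptides (28 tested, median -0.02, adjusted p = 0.68), and 0 of either passed adjusted over the list alone. Mtrr, which reactivates the B12-dependent methionine synthase, had a log2 fold change of 0.43 ± 0.13, and the kappa opioid receptor Oprk1 -0.95 ± 0.30. The same held for chromatin methylation (44 tested, median 0.08), RNA methylation (21 tested, 0.01), inflammation and interferon (36 tested, 0.02), astrocytes (16 tested, -0.02; mean 0.00), microglia (18 tested, -0.08) and myelin (20 tested, -0.12), each at an adjusted p of 0.984 in camera. Adjusted over the list alone, 1 RNA methylation gene was up and 1 down, and 0 passed in the others. The RNA demethylase Alkbh5 stood at 0.33 ± 0.08 and the RNA methyltransferase Nsun3 at -0.37 ± 0.09 (adjusted p = 0.0739 and 0.129, edgeR). The microglial genes Cx3cr1 and P2ry12 stood at -0.25 ± 0.09 and -0.22 ± 0.09 and did not pass. With the correlation preset to 0.01, 11 lists passed for stress under saline, and only the glucocorticoid and clock lists held with an estimated correlation; fry called 2 lists.

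**Figure D3:**
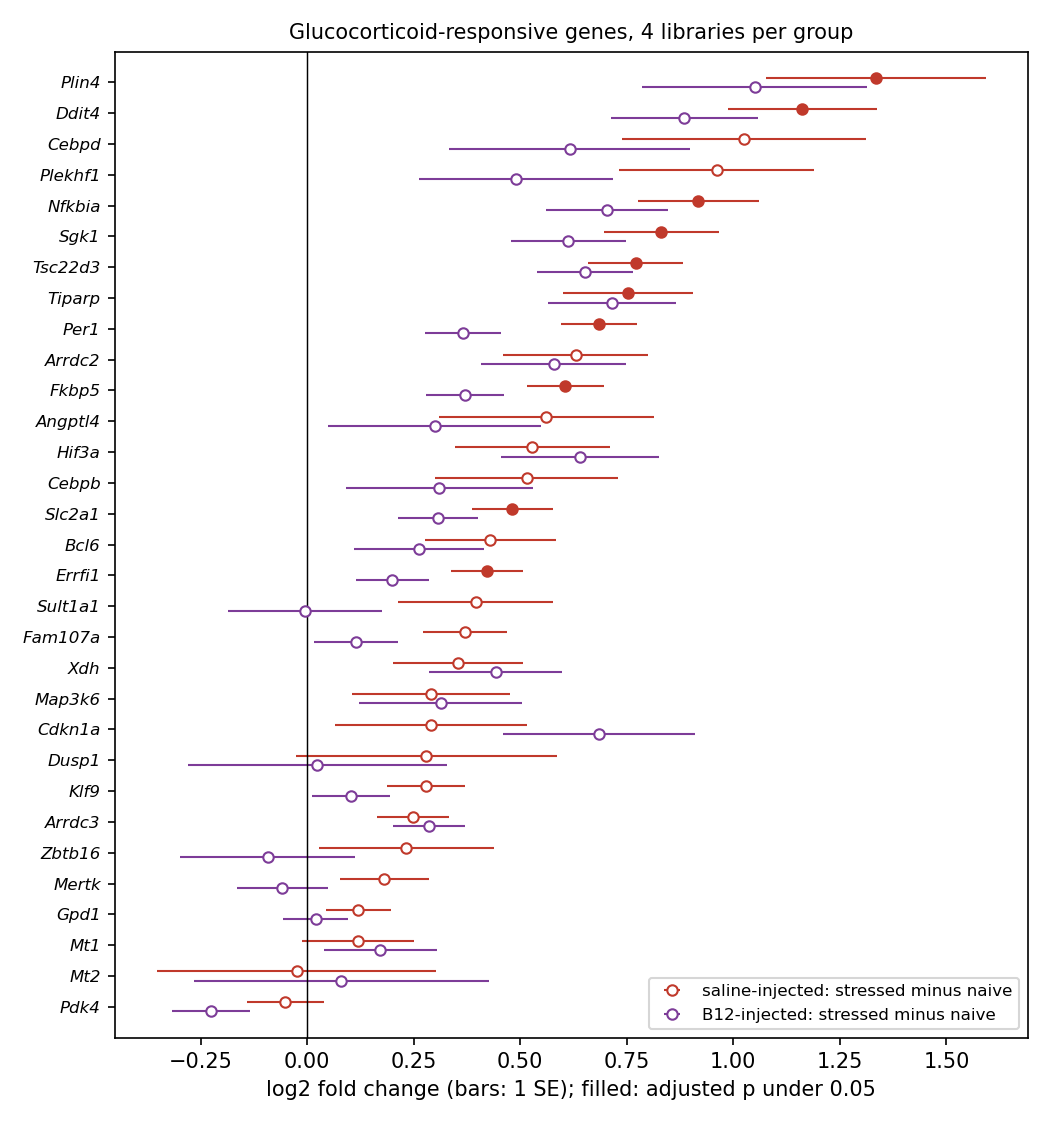
Log2 fold change of stress for the 31 tested glucocorticoid-responsive genes under saline (red) and under vitamin B12 (purple), with bars of 1 SE and 4 libraries per group. Filled points passed an adjusted p of 0.05 over all genes, 10 under saline and 0 under vitamin B12; 29 and 27 of the genes lie above 0.

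The same comparison among mice that received vitamin B12 asks what stress changed in its presence. Klf10, a transcription factor, rose from 35.1 ± 3.25 to 58.2 ± 8.82 CPM (SD, n = 4; log2 fold change 0.73 ± 0.11, SE, adjusted p = 0.0383, edgeR's quasi-likelihood test). Rara rose from 7.41 ± 1.24 to 13.1 ± 1.81 CPM (0.82 ± 0.13, adjusted p = 0.0383, edgeR), Zfp189 from 8.77 ± 0.57 to 15.2 ± 1.83 CPM (0.80 ± 0.13, adjusted p = 0.0383) and Acer2 from 6.66 ± 1.03 to 11.9 ± 1.54 CPM (0.84 ± 0.14, adjusted p = 0.047). These 4 genes passed, with all 4 stressed libraries beyond all naive ones, and all 4 also rose under saline. All 4 calls ended in edgeR with the replicate number as a block and in a fit to these 8 libraries alone. Nearest to the threshold were Tsc22d3 at 0.65 ± 0.11 and the kinase gene Hunk at -0.62 ± 0.11 (adjusted p = 0.058 and 0.0582, edgeR); Klf6 stood at -0.36 ± 0.07, Rasgef1b at -0.56 ± 0.12 and Nell1 at -0.35 ± 0.08. At an unadjusted p under 0.05 there were 1475 genes. DESeq2 called 78 genes and limma voom 171. The count was 0 without naive vitamin B12 library 1, 2 or 3 or stressed vitamin B12 library 2 or 4, 2 without naive vitamin B12 library 4, 12 without stressed vitamin B12 library 1 and 118 without stressed vitamin B12 library 3. Without stressed vitamin B12 libraries 1 and 3 together it was 148.

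Glucocorticoid-responsive genes also rose as a list under vitamin B12. Of 31 members 0 passed over all genes and 14 rose adjusted over the list alone; 27 were positive, at a median log2 fold change of 0.31 (adjusted p = 0.00476, camera with an estimated correlation). Ddit4 stood at 0.88 ± 0.17, Nfkbia, an inhibitor of NF-kappaB, at 0.70 ± 0.14 and Tiparp at 0.71 ± 0.15 (adjusted p = 0.0996, 0.111 and 0.12, edgeR). The list passed camera without each of the 8 libraries in turn, but not without stressed vitamin B12 libraries 1 and 3 together, at a median of 0.25 (adjusted p = 0.0773, camera). The clock list had 6 up and 1 down adjusted over the list alone (median 0.12, adjusted p = 0.285, camera), with Bhlhe41 at 0.43 ± 0.08 and Cry1 at 0.53 ± 0.12. Of 25 heat shock genes 22 were positive and 3 rose adjusted over the list alone (median 0.12, adjusted p = 0.209, camera); the list passed without stressed vitamin B12 library 1 (adjusted p = 0.031). The cold-inducible gene Rbm3 stood at 0.43 ± 0.11 and Hspb1 at 0.79 ± 0.20. Immediate-early genes had 8 up and 1 down adjusted over the list alone (median 0.06, adjusted p = 0.411, camera), Fosb at 0.64 ± 0.14 and Jun at 0.44 ± 0.11. All 13 mitochondrially encoded genes of oxidative phosphorylation were negative, with 0 passed either over all genes or adjusted over the list alone (median -0.18, adjusted p = 0.285, camera). In the vitamin B12, folate and methionine list 35 of 53 were positive and 0 passed, also 0 adjusted over the list alone (median 0.06, adjusted p = 0.411, camera). Mat2a, which makes S-adenosylmethionine, stood at 0.33 ± 0.09 and Amd1, which feeds polyamine synthesis, at 0.22 ± 0.06. With a preset correlation 16 lists passed for this comparison, of which the glucocorticoid list held with an estimated correlation; fry called 1.

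The 69 genes called under saline had the same direction of stress response under vitamin B12 in 69 cases. Their median log2 fold change in the saline direction was 0.44 under vitamin B12 against 0.68 under saline, and 63 passed adjusted over the list alone; they were chosen for their values under saline, so the latter median is not independent of the choice. The reverse choice, the 69 genes of lowest p under vitamin B12, gave medians of 0.51 under vitamin B12 and 0.45 under saline, with 68 in the same direction. Without stressed vitamin B12 libraries 1 and 3, 68 of the 69 kept their direction, at a median of 0.42. Across all 18041 genes, r between the stress responses of the 2 arms was 0.22 (permutation p = 0.0229, adjusted 0.0457; smallest p the permutations can give 0.000816), and Spearman's rho was 0.19 (permutation p = 0.148). Genes are not independent replicates here. Leaving out 1 library ended the call, by the adjusted permutation p, for 10 of the 16: naive saline library 1, 3 or 4 (r = 0.20, 0.17 and 0.22; adjusted permutation p = 0.0735, 0.18 and 0.0637), stressed saline library 1 or 4 (0.18 and 0.22; 0.127 and 0.0653), naive vitamin B12 library 2 or 3 (0.19 for both; 0.111 and 0.104) and stressed vitamin B12 library 1, 2 or 4 (0.18, 0.19 and 0.18; 0.199, 0.0882 and 0.134). Among genes with a mean of at least 5 CPM r was 0.25 and did not pass (permutation p = 0.17, adjusted 0.34). With the replicate number as a block r was 0.22 and did not pass either (permutation p = 0.345, adjusted 0.691).

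**Figure D4:**
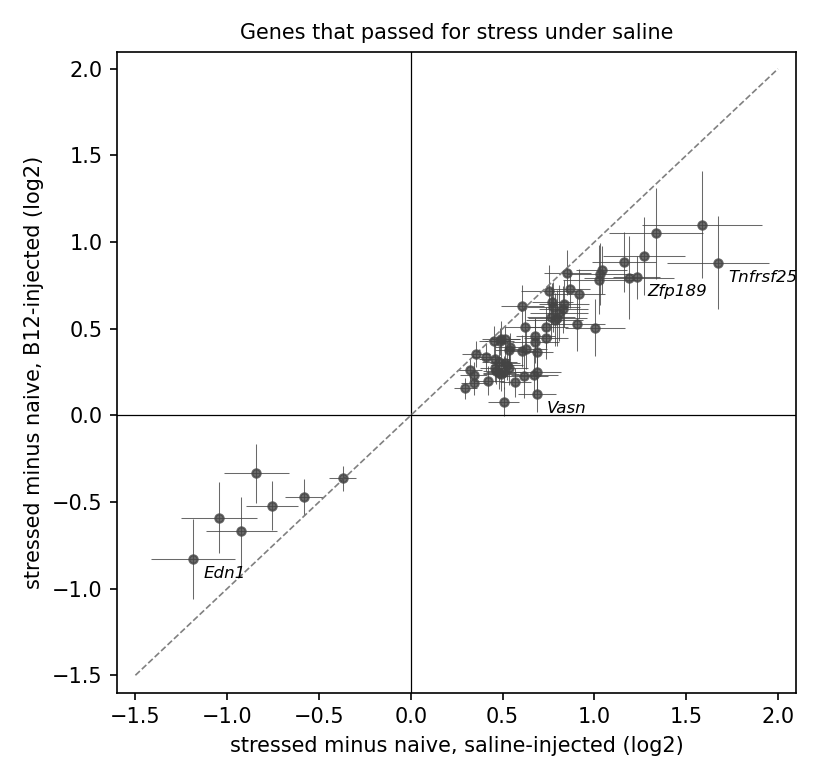
Log2 fold change of stress under saline (x axis) and under vitamin B12 (y axis) for the 69 genes that passed under saline, with bars of 1 SE and a dashed line of equal change. All 69 lie in the quadrants of equal sign, and 67 lie closer to 0 under vitamin B12. The genes were chosen for their values under saline, so the latter count is not independent of the choice.

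Vitamin B12 in stressed mice, the comparison that bears on the series title, had 0 genes past edgeR's threshold. The lowest adjusted p was 0.848 in edgeR, 1036 genes had an unadjusted p under 0.05, DESeq2 called 2 and limma voom 1. The genes of lowest p were all below significance: Pde2a, a cyclic nucleotide phosphodiesterase, went from 7.75 ± 0.966 CPM in stressed saline to 4.29 ± 1.05 in stressed vitamin B12 (SD, n = 4), a log2 difference of -0.85 ± 0.20 (SE). The transcription factor Foxp2 went from 4.44 ± 0.426 to 8.69 ± 2.58 CPM, a difference of 0.96 ± 0.23. Shank3, a postsynaptic scaffold, stood at -0.46 ± 0.11, Mmel1 at -1.11 ± 0.28, the transcription factors Nfic and Pou6f1 at -0.37 ± 0.09 and -0.26 ± 0.06, Etohd2 at 0.82 ± 0.20, the amylase gene Amy1 at 0.62 ± 0.16, Zfp772 at 0.35 ± 0.09 and Fgfr1op at 0.35 ± 0.09. Named after their values were seen, the calls of other tools were Pou6f1 and Clic6 in DESeq2 (-0.25 ± 0.06 and -5.49 ± 1.20, adjusted p = 0.0451 for both) and the mitochondrial carrier gene Ucp2 in limma voom (-0.67 ± 0.09, adjusted p = 0.00584). Without stressed vitamin B12 libraries 1 and 3, Ucp2 passed edgeR's test at -0.70 ± 0.10 (adjusted p = 0.00603) as the 1 gene called, and 2572 genes had an unadjusted p under 0.05.

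No gene list passed camera for vitamin B12 in stressed mice. Glucocorticoid-responsive genes were negative in 26 of 31 cases, at a median of -0.17 (adjusted p = 0.205, camera), with 0 passed over all genes and 0 adjusted over the list alone. Fam107a, a stress-responsive actin-associated gene, stood at -0.28 ± 0.10 and Pdk4 at -0.22 ± 0.09. Mitochondrially encoded genes of oxidative phosphorylation were negative in 12 of 13 cases (median -0.21, adjusted p = 0.205, camera), with 0 passed over all genes and 9 down adjusted over the list alone. The gene mt-Nd2, a subunit of respiratory complex I, stood at -0.27 ± 0.09. Synapse genes were negative in 37 of 44 cases, with 2 down adjusted over the list alone, Shank3 and Shank1 (-0.41 ± 0.10) having the lowest p (median -0.12, adjusted p = 0.551, camera). Synapse genes were low in stressed vitamin B12 library 3, at the -0.44 given above. The 11 olfactory bulb markers had a median of 2.68 with 0 passed over all genes and 6 up adjusted over the list alone (adjusted p = 0.611, camera). Doc2g at 4.53 ± 1.27 and Th at 4.57 ± 1.32 were high in stressed vitamin B12 library 1. GABAergic interneuron markers, high in the same library, had a median of 0.34 over 21 tested members and glutamatergic neuron markers -0.15 over 19 (mean 0.12), both at an adjusted p of 0.758 in camera. Of these, 2 glutamatergic markers were up and 2 down adjusted over the list alone, and 0 GABAergic ones. The 11 choroid plexus markers, high in stressed saline libraries 3 and 4, had a median of -1.85 with 10 down adjusted over the list alone (adjusted p = 0.504, camera).

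Of the remaining lists, myelin genes were positive in 20 of 20 cases for vitamin B12 in stressed mice (median 0.40, adjusted p = 0.611, camera), with Ugt8a, an enzyme of myelin lipid synthesis, at 0.40 ± 0.18. These genes were high in stressed vitamin B12 libraries 1 and 3. Thyroid hormone and retinoid genes had a median of -0.09 (adjusted p = 0.291, camera), among them Cyp26b1, which degrades retinoic acid, at -0.52 ± 0.21 and Slco1c1, a thyroxine transporter, at -0.24 ± 0.10. Nuclear-encoded oxidative phosphorylation genes gave a median of 0.05 over 77 tested members (adjusted p = 0.804, camera) and the cytosolic ribosome 0.05 over 79 (adjusted p = 0.782), both high in stressed vitamin B12 library 3. Ependyma (8 tested, median -0.07, adjusted p = 0.771), meningeal fibroblasts (18, -0.21, 0.782), mural cells (11, -0.17, 0.611), striatum (18, -0.06 with a mean of 0.02, 0.611) and blood (5, -0.34, 0.758) did not pass camera either. In the vitamin B12, folate and methionine list the median was 0.03 over 53 genes (adjusted p = 0.771, camera), with Cubn, the intestinal and renal receptor of the B12 carrier, at 0.89 ± 0.42. In all lists of this paragraph 0 members passed, over all genes or adjusted over the list alone. With a preset correlation 6 lists passed for vitamin B12 in stressed mice, none of which held with an estimated correlation.

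Whether vitamin B12 turned the stress response back was examined across genes between stress under saline and vitamin B12 in stressed mice. The correlation was -0.41. Both comparisons use the stressed saline libraries, and 1000 simulated sets of unchanged groups sharing libraries in this way gave a mean of -0.50 with 95% of values between -0.77 and -0.04; 728 of them lay at or below the observed value. With the stressed saline libraries split so that no library was shared, the 6 splits gave a mean of -0.07, from -0.12 to -0.01. The observed correlation lay within the simulated range. In the simulated sets, however, any library could fall in the shared group, including stressed vitamin B12 libraries 1 and 3. Their deviations from the median library had SDs across genes of 0.56 and 0.52, against 0.24 to 0.31 in the other 14. In the data these libraries lie outside the shared group, so the simulated range cannot decide whether a reversal was present.

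Vitamin B12 in naive mice had 0 genes past edgeR's threshold, 242 at an unadjusted p under 0.05, 0 in DESeq2 and 0 in limma voom. The sodium channel gene Scnn1a had a log2 difference of 0.80 ± 0.22, from 0.812 ± 0.124 CPM in naive saline to 1.42 ± 0.199 in naive vitamin B12 (SD, n = 4). P2ry14, a receptor of UDP-sugars, had -0.63 ± 0.19, from 2.73 ± 0.454 to 1.76 ± 0.231 CPM; the adjusted p was 1 in edgeR for both. Galnt4 stood at 0.48 ± 0.16, Snord91a at 0.43 ± 0.15, the mitochondrial import gene Timm10b at 0.36 ± 0.13, Rn7sk at 0.99 ± 0.35, Ms4a6d at -0.98 ± 0.33, Faap100 at -0.37 ± 0.12, Zfp13 at -0.24 ± 0.08 and the ubiquitin ligase gene Rchy1 at -0.21 ± 0.07. In the vitamin B12, folate and methionine list 29 of 53 genes were negative, at a median of -0.01 (adjusted p = 0.962, camera), with 0 passed over all genes and 0 adjusted over the list alone. Mmachc, which processes cobalamin in the cell, stood at -0.18 ± 0.10. Glucocorticoid-responsive genes were split between 16 positive and 15 negative (median 0.00, adjusted p = 0.962, camera), with 0 passed either way. Immediate-early genes were positive in 29 of 35 cases (median 0.13, adjusted p = 0.962, camera), also with 0 passed either way, and Egr2 stood at 0.59 ± 0.30. Myelin genes had a median of 0.22 and were high in naive vitamin B12 library 3. In camera 0 lists passed, 4 with a preset correlation and 0 in fry. The vitamin B12 responses of naive and stressed mice had a correlation across genes of 0.00 (permutation p = 0.993, adjusted 0.993) and a rho of -0.02 (permutation p = 0.925).

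The interaction asks whether the vitamin B12 response differed between stressed and naive mice. Trpm6, a magnesium channel, had the lowest p, at a log2 difference of -1.54 ± 0.36, from 1.20 ± 0.213, 1.69 ± 0.321, 1.95 ± 0.274 and 0.924 ± 0.395 CPM in naive saline, stressed saline, naive vitamin B12 and stressed vitamin B12 (SD, n = 4; adjusted p = 0.999, edgeR). The small GTPase gene Rab43 stood at -1.19 ± 0.30, Vasn, which binds TGF-beta, at -0.56 ± 0.15, the zinc finger gene Zfp703 at -0.43 ± 0.12 and B3gnt3 at -1.25 ± 0.35. The histone chaperone gene Asf1a stood at 0.81 ± 0.22, Faap100 at 0.59 ± 0.17, Gt(ROSA)26Sor at 0.55 ± 0.15, Rap1a at 0.48 ± 0.15 and Zfp184 at 0.75 ± 0.23. No gene passed edgeR's test, 561 had an unadjusted p under 0.05, and 0 passed in DESeq2 and 0 in limma voom. Glucocorticoid-responsive genes were negative in 24 of 31 cases, at a median of -0.21 (adjusted p = 0.371, camera), with 0 passed over all genes and 0 adjusted over the list alone. Per1 stood at -0.32 ± 0.13. Among the 69 genes called for stress under saline, 0 passed for the interaction adjusted over the list alone. Shank1 and Shank3 stood at -0.48 ± 0.15 and -0.50 ± 0.16, in a synapse list with a median of -0.13 (adjusted p = 0.732, camera). Cyp26b1 stood at -0.78 ± 0.30, in a thyroid hormone and retinoid list with a median of -0.09 (adjusted p = 0.371, camera); 0 of either list passed over all genes or adjusted over the list alone. In camera 0 lists passed, 9 with a preset correlation and 0 in fry.

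Averaged over both injections, stress raised Depp1, a gene of the FOXO response, by a log2 fold change of 1.64 ± 0.23, with levels of 0.551 ± 0.182 and 1.55 ± 0.275 CPM in naive and stressed saline and 0.459 ± 0.182 and 1.58 ± 0.518 CPM in naive and stressed vitamin B12 (SD, n = 4; adjusted p = 0.000988, edgeR). Tnfrsf25 rose by 1.28 ± 0.19, Plin4 by 1.19 ± 0.18, the endothelial gene Apold1 by 1.14 ± 0.23 and Maff by 1.09 ± 0.16. Edn1 fell by 1.01 ± 0.16, the B-cell and microglial receptor gene Cd180 by 0.71 ± 0.17, Plekhs1 by 0.67 ± 0.14 and Opn3 by 0.64 ± 0.10. Either 7 or 8 of the 8 stressed libraries lay beyond all 8 naive ones for each of these genes. In all, 232 genes passed edgeR's test, 175 up and 57 down, at a median size of 0.43 on the log2 scale, and they include the 69 called under saline. DESeq2 called 413 and limma voom 999. The count was 707 without stressed vitamin B12 library 3, 1007 without stressed vitamin B12 libraries 1 and 3, 85 without stressed saline libraries 3 and 4, and 125 with the choroid plexus covariate. It was 145, 152 or 142 without naive saline library 1, 3 or 4, 134, 153 or 130 without stressed saline library 1, 2 or 4, and 154, 142 or 151 without naive vitamin B12 library 1, 2 or 4. Cd180 and Plekhs1 lost the call in 13 and 7 of the 16 fits without a library, and the other genes named here kept it. Vitamin B12 averaged over both histories had 0 genes past edgeR's threshold, 513 at an unadjusted p under 0.05, 0 in DESeq2 and 0 in limma voom.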

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

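The tests of choroid plexus and olfactory bulb tissue, of Ttr and of olfactory markers in every mouse, of gene length bias and of lessened glucocorticoid-responsive genes, the fits without libraries that stood apart, and the count at an adjusted p under 0.1 without them, were chosen after the results were seen; the counts of other splits were not.

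Ttr was high in 2 of the 4 stressed saline libraries, 3 and 4. A rise caused by stress in every stressed saline mouse is argued against, since 2 libraries lay above the highest naive saline library and the other 2 lay within the naive range. Choroid plexus tissue taken along in libraries 3 and 4 may be the source: the excess over the other libraries was 7.67 times larger in library 4 than in library 3 for Ttr, and 7.94 times at the median of the 11 other choroid plexus markers, which range from 3.42 to 9.6. Clic6 reached 33.4 CPM and Enpp2 951 CPM in library 4, and the prefrontal cortex also transcribes part of this list, with Enpp2 at a median of 206 CPM in the other 14 libraries. A response of choroid plexus to stress in these mice stays open, as does the way the tissue came to be in these libraries.

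Stressed vitamin B12 libraries 1 and 3 stood apart from the other 14. Olfactory bulb tissue in library 1 is a candidate explanation, with the 11 markers at a median log2 excess of 4.35, and Calb2 and Cdhr1 at 290.5 and 284 CPM. A rise of these markers by vitamin B12 after stress in every mouse is argued against, since 1 of the 4 libraries lay above the other groups. Gene length bias is a candidate explanation for library 3, at a rank correlation of -0.51. What brought the bias about was not tested.

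Few genes passed in the comparisons that use the stressed vitamin B12 group. Spread added by libraries 1 and 3 of that group may account for the count under stress with vitamin B12, which went from 4 to 148 without them. Without them this stress response also followed gene length at a rank correlation of 0.21, against -0.11 with all libraries. For vitamin B12 in stressed mice the same spread stays open. Without libraries 1 and 3, 1 gene passed, Ucp2, fewer than the 5 set beforehand as the bound against this explanation. That bound overlooked genes just past the threshold, with 79 at an adjusted p under 0.1 in edgeR. The lowest value was 0.00603 against 0.848 with all libraries. Libraries 2 and 4 of the group, which this fit kept, had length correlations of 0.23 and 0.29. The vitamin B12 response followed gene length at a rank correlation of 0.24 in this fit, against -0.09 with all libraries. Whether this trend contributed to the 79 genes was not tested. Whether vitamin B12 lessened the response of glucocorticoid-responsive genes cannot be told apart from no difference, since the list gave an adjusted p of 0.371 in camera for the interaction, at a median of -0.21.

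Other splits of the libraries set these counts beside chance. Only the real grouping gave as many genes for stress under saline (69, highest other split 0, 1 of 35 splits). The same held for the genes of stress under vitamin B12 (4, highest other 1, 1 of 35). It held too for stress averaged over both injections (232, highest other 0, 1 of 50). Among lists it held for stress under saline (2, highest other 1, 1 of 35) and under vitamin B12 (1, highest other 0, 1 of 35). A share of 1 of 35 or 1 of 50 is the smallest that so few splits can give. Chance is thus argued against but not excluded. The 4 genes of stress under vitamin B12 and the clock list under saline lost their calls in most fits without a library. For the comparisons with 0 genes in edgeR the count of splits says nothing about chance, since every split gives at least 0: vitamin B12 in stressed mice (highest other 1; 35 of 35), in naive mice (highest other 4; 35 of 35), averaged (highest other 0; 50 of 50) and the interaction (highest other 2; 50 of 50).

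A single library lay far from the other 3 of its group in 49 of 612 groups of 4, where chance gives this for about 1 in 20 groups, here 30.6. Of these, 15 fell in stressed vitamin B12 library 1, 7 in library 3 of that group and 6 in naive vitamin B12 library 3. In stressed vitamin B12 library 1, Syt6 stood at 145 CPM, Calb2 at 271, Doc2g at 99.8, Th at 71.8, Tiparp at 27, Mat2a at 174 and Asf1a at 10.7, above the others. Below them in this library were Tnfrsf25 at 1.61 CPM, Fam78a at 6.55, Klf6 at 47.4, Rasgef1b at 45.2 and Hspa5 at 253. Its mean log2 CPM was 6.08 for olfactory bulb markers, 5.76 for GABAergic and 6.31 for glutamatergic neuron markers. Stressed vitamin B12 library 3 had Alkbh5 at 59.7 CPM, Sdf2l1 at 12, a length correlation of -0.51, and list means of 6.18 for nuclear oxidative phosphorylation, 3.29 for the ribosome, 4.61 for stress neuropeptides and 5.49 for the unfolded protein response. Library 4 of the group had Zfp184 at 3.79 CPM.

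Among naive vitamin B12 libraries, number 3 had Opn3 at 5.57 CPM, Foxp2 at 8.89, Ugt8a at 31.6 and Calb2 at 20.8, with list means of 5.63 for myelin and 4.54 for endothelium. Number 1 had Ier5l at 21.6 CPM, mt-Atp8 at 11.9, Cd180 at 2.28 and a glucocorticoid list mean of 4.25, and number 2 had Fkbp5 at 26.1 CPM. In stressed saline, library 1 had Mtrr at 10.5 CPM, Aspa at 5.53, Cd180 at 1.2 and a synapse list mean of 8.59. Library 2 of that group had Maff at 3.83 CPM, Neurod2 at 118 and Vasn at 15.9, library 3 an oligodendrocyte precursor mean of 4.35, and library 4 Pdia4 at 44.4 CPM. In naive saline, library 1 had Sp8 at 0.694 CPM and Rps20 at 18, library 2 Arl4d at 15.3, library 3 Zfp772 at 8.57 and library 4 Alkbh5 at 62.5.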

How the results depend on the processing

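The fits without stressed vitamin B12 libraries 1 and 3, without stressed saline libraries 3 and 4 and without these 4, and the clock list without shared genes, were tests chosen after the results were seen. Over the named genes and the glucocorticoid and clock lists, apart from the counts, correlations and Ttr values given below, 3548 values under other settings kept direction and side of the threshold, 117 passed newly, 198 no longer passed, 21 turned in sign without passing and 0 passed and reversed. For the values below the cause was not tested, except that fits without libraries have fewer samples.

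For stress under saline, 69 genes became 168 in DESeq2, 479 in limma voom, 105 at an adjusted p under 0.1, 515 with the compared groups alone, 23 with the choroid plexus covariate, 1 without stressed saline libraries 3 and 4 and 224 without the 4 libraries. For stress under vitamin B12, 4 became 78 in DESeq2, 171 in voom, 2 with limma-trend, 11 without a filter, 7 with 1 CPM in 8 libraries, 15 at an adjusted p under 0.1, 0 with the compared groups alone, 148 without stressed vitamin B12 libraries 1 and 3 and 138 without the 4. For vitamin B12 in stressed mice, 0 became 2 in DESeq2, 1 in voom and 1 without stressed vitamin B12 libraries 1 and 3. Stress averaged, 232, became 413 in DESeq2, 999 in voom, 350 at an adjusted p under 0.1, 125 with the covariate, 1007, 85 and 805 without the first pair, the second pair and the 4 libraries; vitamin B12 averaged became 1 without the 4.

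The 2 lists of stress under saline became 1 with the covariate, 1 without stressed saline libraries 3 and 4, 1 without the 4 libraries and 1 with the clock list without shared genes. The 1 list of stress under vitamin B12 became 0 without stressed vitamin B12 libraries 1 and 3 and 0 without the 4. With a preset correlation 11, 6, 4, 16 and 9 lists passed for stress under saline, vitamin B12 in stressed and in naive mice, stress under vitamin B12 and the interaction. Ttr under saline was 9.3 in DESeq2, 5.15 in voom, 3.14 with limma-trend and 1.96 with the choroid plexus covariate. It was -0.2 without stressed saline libraries 3 and 4 and -0.23 without the 4. For vitamin B12 in stressed mice these last 3 settings gave -0.49, 1.56 and -2.11, and for the interaction -2.07, -0.92 and -4.59. The stress agreement no longer passed at a mean of at least 5 CPM (0.25, permutation p = 0.17) or as rho (0.19, permutation p = 0.148), and that of vitamin B12 was -0.05 and -0.02.

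With the replicate number as a block, stress under vitamin B12 had 0 genes, stress under saline 1 list, and the stress agreement was 0.22 with a permutation p of 0.345. Same-numbered libraries of different groups correlated at a mean of 0.009 over 24 pairs, with 5 of the 16 libraries closest to one of their own number.

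Leaving out each library in turn gave 24 to 45 genes for stress under saline, 0 to 118 for stress under vitamin B12 and 130 to 707 for stress averaged, and 0 to 0 in edgeR for vitamin B12 in stressed mice, in naive mice, averaged and for the interaction (1036, 242, 513 and 561 at an unadjusted p under 0.05 with all libraries; DESeq2 2, 0, 0 and 0). Lists numbered 1 to 3 for stress under saline, 1 to 2 under vitamin B12 and 0 to 0 in the others. Ttr ranged from 6.58 to 9.68 for stress under saline, -11.06 to -5.27 for vitamin B12 in stressed mice, 0.01 to 2.91 in naive mice, -4.29 to 1.29 for stress under vitamin B12 and -13.54 to -7.75 for the interaction. The stress agreement ranged from 0.17 to 0.24, that of vitamin B12 from -0.13 to 0.14, and the correlation of stress with vitamin B12 in stressed mice from -0.51 to -0.31. Depth limits Ttr in stressed vitamin B12 library 2, where 0 reads allow up to 0.159 CPM.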

Other observations

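The fits without libraries that stood apart were tests chosen after the results were seen. Blood genes lay above the other 15 libraries by a median log2 difference of 0.95 in stressed saline library 3, with 5 of 5 members above all of them. Responses followed gene length at a rank correlation of 0.24 for vitamin B12 in naive mice and 0.14 for stress under saline. The value was -0.09 for vitamin B12 in stressed mice and -0.11 for stress under vitamin B12. Without stressed vitamin B12 libraries 1 and 3 it was 0.24 for the former and 0.21 for the latter.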
